A study of Mus musculus with 9 samples.

How the data were processed

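Bulk RNA-seq had been done on dissected anterior segments of mouse eyes at postnatal day 0, from 3 wildtype samples and 6 samples heterozygous for Col4a1 G1344D. Per the labels' protocols, each sample pooled 4 eyes from 2 mice, the lens was removed, tissue was kept in RNAlater, total RNA was extracted with a column kit for small samples and libraries followed standard Illumina procedures. The deposited values are raw read counts per Ensembl gene, whole numbers with no normalization, in 1 column per sample. Per the submitters' processing notes, STAR 2.6.1, HTSeq 0.6.1, DESeq2 1.6.3 and the mouse build GRCm38 (mm10) were used, with no roles given. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or are antisense to each other cannot be told apart by their reads. Samples were grouped by the genotype in their labels, and 0 columns were left without a sample.

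The counts summed to 28356439, 25995340 and 26700694 in wildtype 1 to 3 and to 29443004, 31561898, 35306935, 28877043, 34730227 and 28440874 in mutants 1 to 6. Gene symbols, positions and exon lengths came from a GENCODE annotation of GRCm38, which held 34490 of the 35275 identifiers. Genes without a symbol took between 0.0587% and 0.069% of the counts. Genes of near-identical sequence, such as the alpha globin pair, share reads. Pairs of libraries within a group differed by more than sampling noise in a chi-square test of their counts, so each library was used as 1 replicate.

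The main test was edgeR 4.0.16 (R 4.3.3), with TMM normalization, the default filter on low counts by group, a robust quasi-likelihood fit with genotype as the single term, and Benjamini-Hochberg adjustment at 0.05 over 15825 genes. Values per gene are CPM, computed from the deposited counts with TMM library sizes, as mean and SD over libraries. A log2 fold change comes from the fit. Genes with few wildtype counts were given as a ratio of summed counts with an exact 95% interval, which covers counting error only. Col4a1 and Col4a2 were also tested by an exact two-sided permutation of log2 CPM over all 84 splits.

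Gene lists for pathways, matrix, stress, immune and cell type markers were fixed before the data were examined, 42 in all, of which 41 with at least 3 tested members entered the tests and 1, of sex-linked genes, served to check libraries. Lists were tested on log2 CPM with a prior count of 2 by camera (limma 3.58.1) with a preset correlation of 0.01, which compares a list with all other genes, and again with the correlation estimated for each list. Fry was run beside it and asks whether a list's genes move, on balance, one way, without comparing them with other genes. A further 6 lists were added after the data had been seen, and their p-values were adjusted over these 6 only. The rule for named genes, fixed before the data were examined, took Col4a1 and Col4a2, and in each direction the 10 genes with the largest log2 fold change among those past the test, with a mean of at least 1 CPM and no overlap between the groups. It skipped clone and model names, pseudogenes and sex-linked genes. For each list described it took up to 4 tested members with the lowest p.

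Alternatives planned before the data were examined were other scaling factors, DESeq2 1.42.0, limma-voom with quality weights, weaker and stricter filters, other thresholds, a test against a fold of 1.2, a replicate block, score covariates and leaving out each library. Alternatives added afterwards removed from each library a smooth trend of expression on gene length (mgcv 1.9.3), with or without GC content, using total exon length or the length of the annotated principal transcript, added the split of libraries on ribosomal RNA as a covariate, or left out Gm42418 and Lars2. That split was set at 1% of counts on Gm42418.

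The tests were checked on simulated counts of mutant over wildtype. Each gene was drawn independently of the others, while the basement membrane list, for one, had an estimated correlation of 0.55 in the data. The simulated list counts therefore do not show how often camera with the preset correlation calls lists of correlated genes. With 15611 genes, 54.5% of genes changed by 1.5-fold and 71.1% of those changed by 2-fold were recovered, and 7.52% of calls were unchanged genes. With no change, 0 of 15668 genes and 0 lists were called (edgeR and camera). With only a length trend, 5 of 15630 genes and 3 lists were called, and after the length correction 0 genes and 0 lists (edgeR and camera). With a trend and the correction, over 15613 genes, 53.1% of 1.5-fold and 70.7% of 2-fold changes were recovered, and 1.61% of calls were unchanged genes. The simulated trend was made with the same kind of smooth that the correction removes, so its removal was largely fixed in advance. The simulated spread was taken from data that hold the trend. These runs therefore do not show how many calls the trend gives in the data.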

Results

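RNA was measured by bulk sequencing in the anterior segment of newborn mouse eyes at postnatal day 0. The dissected tissue held the cornea, iris, ciliary body and drainage structures, and the lens had been taken out. The 9 libraries came from 3 wildtype samples and 6 samples heterozygous for the G1344D missense change in Col4a1, the gene for the alpha-1 chain of type IV collagen. Each sample pooled 4 eyes from 2 mice, so the p-values measure the spread between pools. The read counts per gene, as deposited, summed to between 25995340 and 35306935 per library over 35275 genes, and 15825 genes had enough counts to be tested. The comparison asks which genes differ between mutant and wildtype anterior segments at birth, and a list of TGF-beta target genes was fixed for it before the data were examined, since TGF-beta signalling is a known question for this mutant line.

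Col4a1 and its partner Col4a2, whose products assemble into the main type IV collagen of basement membranes, were both higher in the mutant. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826 of GRCm38, minus strand) rose from 626 ± 92.7 CPM (SD, n = 3) to 1030 ± 82.7 CPM (SD, n = 6), a fold of 1.65 (log2 0.72, SE 0.105, edgeR adjusted p = 0.000876). Col4a2 (ENSMUSG00000031503, chromosome 8, 11312805 to 11449287) rose from 513 ± 89.7 to 819 ± 69.8 CPM, a fold of 1.6 (log2 0.67, SE 0.11, edgeR adjusted p = 0.00166). All 6 mutant libraries lay above all 3 wildtype libraries for both genes, and the exact two-sided permutation p of 0.0119 is the smallest that 84 splits can give. The annotated spans of both genes overlap at their starts, and whether counting used strand is not given in the sources used here, so reads from that short stretch are uncertain. The mutation is a missense change, so these RNA levels do not check the labels.

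Across all tested genes, 3034 differed between the groups (edgeR quasi-likelihood test, adjusted p under 0.05), 1535 higher and 1499 lower in the mutant. Most changes were small: 415 of the higher and 361 of the lower genes changed by 1.5-fold or more, and 125 and 49 by 2-fold or more. The groups did not overlap for 3486 genes, 22.0% of those tested, where chance gives 2.38% on average. Genes are not independent, and many moved together along the gene length trend given below, so this share was not tested. The number of calls depended on single wildtype libraries: 538 genes were called without wildtype 1, 303 higher and 235 lower, and 1669 without wildtype 3, 849 higher and 820 lower.

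The 10 genes with the largest rises under the fixed rule were Marco, Treml4, Ly9, Adam8, Il18bp, Hmox1, Clec4d and the alpha globin genes Hba-a1, Hba-a2 and Hba-x. Hmox1, the haem oxygenase that breaks haem down, rose 7.91-fold from 48.2 ± 1.64 to 382 ± 73.4 CPM (adjusted p = 9.2e-09). Clec4d, a C-type lectin receptor of myeloid cells, rose 7.43-fold, Adam8 8.29-fold, Ly9, a lymphocyte surface antigen, 9.08-fold, and Il18bp, which binds interleukin 18, 8.01-fold. The size of some rises leaned on single libraries: the log2 fold change of Ly9 went from 3.18 to 4.10 without wildtype 1, that of Il18bp from 3 to 3.82 without wildtype 3, and that of Hba-x from 2.61 to 3.60 without wildtype 1. The scavenger receptor gene Marco had 2 counts over the wildtype libraries and 835 over the mutant libraries, a ratio of 181 with a 95% exact counting interval of 50 to 1500. Treml4 had 6 and 370 counts, a ratio of 26.8 with an interval of 12.2 to 73.5. All wildtype counts of both genes lay in wildtype 3, and these intervals cover counting error only, not the spread between libraries. Hba-a1, Hba-a2 and the embryonic Hba-x rose 6.92-fold, 6.52-fold and 6.09-fold (adjusted p = 0.022, 0.0135 and 0.00211). Hba-a1 and Hba-a2 are near-identical copies, so their split of reads is uncertain.

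The largest falls were smaller in size. C1ql2, a C1q-like secreted protein gene, fell 3.13-fold from 5.03 ± 1.18 to 1.61 ± 0.495 CPM (adjusted p = 0.00136), and Vwde fell 3.04-fold (adjusted p = 0.00217). Ucma, a cartilage matrix protein gene, fell 2.94-fold, the hormone gene Fgf21 2.75-fold, Angptl6 2.64-fold and the nonagouti gene, with the symbol a, which controls pigment type, 2.46-fold. Ramp1, a receptor activity-modifying protein gene, fell 2.42-fold, Prr32 2.38-fold, Cgref1 2.21-fold and Rit2 2.19-fold. Of the 20 genes with the largest changes, 10 lost their call when wildtype 1 was left out: Hba-a1, Hba-a2, Ucma, Fgf21, Angptl6, nonagouti, Ramp1, Prr32, Cgref1 and Rit2. Hba-a1 also lost it without wildtype 2 or 3, and Prr32 and Rit2 without wildtype 3. Ucma lost it as well without wildtype 3 or mutant 3 or 6, Ramp1 without wildtype 2 or 3 or mutant 4, 5 or 6, and Angptl6 without wildtype 2 or 3 or mutant 1, 3, 4 or 5. Ucma, Angptl6 and Ramp1 further lost it once exon length was removed (adjusted p = 0.0615, 0.0794 and 0.0606).

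Basement membrane genes rose as a group. Of 33 measured genes for basement membrane components other than type IV collagen, 24 rose and 1 fell, with a median log2 fold change of 0.45 (camera adjusted p = 3.9e-10; adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 27 rose and 1 fell. The member that fell, Smoc2, went from 215 to 165 CPM, is named after its value was seen, and lost its call without wildtype 1 or 2 or mutant 3. Hspg2, which encodes the heparan sulfate proteoglycan perlecan, rose 1.99-fold from 243 ± 39.9 to 485 ± 99.7 CPM (adjusted p = 0.00115). Frem2 rose 1.68-fold, the laminin chain gene Lama4 1.72-fold, and the nidogen gene Nid1 1.55-fold from 508 ± 49.9 to 789 ± 97.3 CPM. Of the 6 type IV collagen genes, 5 rose and 0 fell (camera adjusted p = 0.00051; adjusted p = 0.51 with an estimated correlation; 6 rose and 0 fell adjusted over the list alone). Besides the mutated gene and its partner, these included Col4a5, up 1.39-fold, and Col4a4, up 1.62-fold. Without wildtype 1, 10 of the basement membrane genes and 3 of the type IV collagen genes were called higher, and Col4a4 lost its call. With exon length removed, 17 of the 33 basement membrane genes were called higher, with a median of 0.33.

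**Figure D1:**
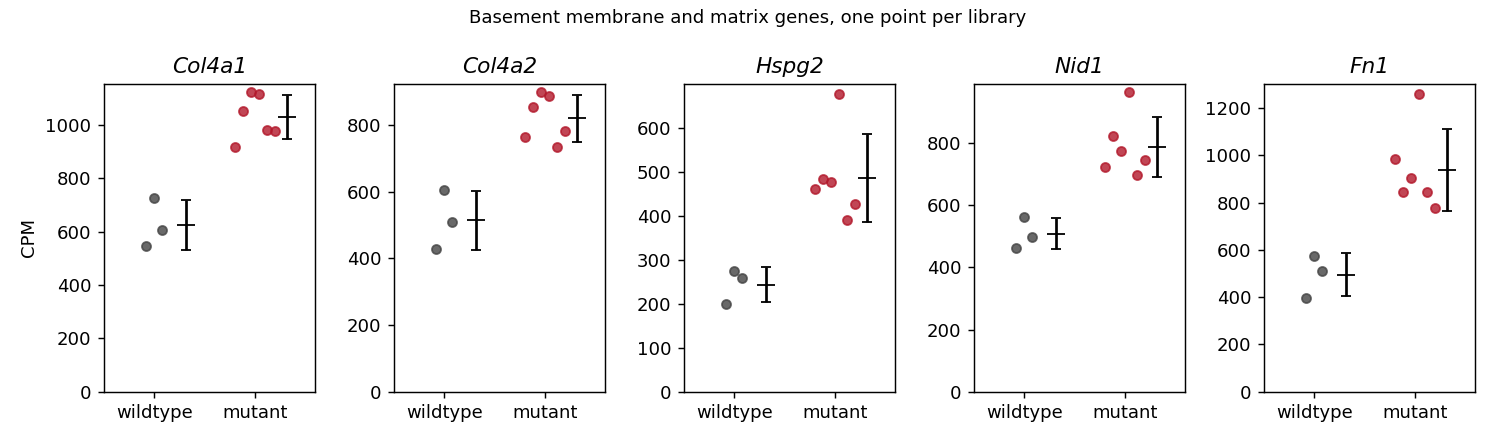
CPM of 5 matrix genes in each of the 3 wildtype and 6 mutant libraries, with the group mean and SD as a bar beside the points. For Col4a1 the mutant mean was 1030 CPM against 626 CPM in wildtype, and every mutant library lies above every wildtype library in all 5 panels.

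Matrix remodelling genes moved too. Of 26 genes for matrix proteases and their inhibitors, 10 rose and 1 fell, against 11 and 1 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.51 with an estimated correlation). Adamts1 rose 1.49-fold, the protease inhibitor gene Timp3 1.40-fold and Adamts4 1.62-fold, and Mmp23 fell 1.93-fold from 25.8 ± 3.41 to 13.4 ± 1.41 CPM (adjusted p = 0.000354). Without wildtype 1, 3 genes of this list were called higher and 1 lower, and without wildtype 3 these counts were 5 and 1. Fibrillar and associated collagens showed no common direction: 2 of 22 rose and 3 fell (camera adjusted p = 0.83; 2 and 3 adjusted over the list alone). Among them Col8a1, a collagen of the corneal endothelial basement membrane, rose 1.44-fold and Col12a1 1.57-fold, while Col27a1 fell 1.63-fold. Col12a1 and Col27a1 lost their calls without wildtype 1, where 1 gene of the list was called higher and 0 lower (edgeR), and without wildtype 3 these counts were 2 and 2.

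TGF-beta target genes rose on balance. Of 35 measured targets, 14 rose and 3 fell (camera adjusted p = 0.00017; adjusted p = 0.51 with an estimated correlation), and 16 rose and 3 fell adjusted over the list alone. Thbs1, whose product activates latent TGF-beta, rose 2.23-fold from 120 ± 7.03 to 269 ± 47.7 CPM (adjusted p = 0.000145). The fibronectin gene Fn1 rose 1.90-fold from 494 ± 91.0 to 937 ± 173 CPM (adjusted p = 0.00153). The versican gene Vcan rose 1.82-fold and Skil, a feedback repressor of the pathway, 1.42-fold. The targets that fell, named after their values were seen, were Id1, 1.41-fold lower, and the contractile genes Acta2 and Tagln, 1.26-fold and 1.36-fold lower. Id1 lost its call without wildtype 1, Acta2 without wildtype 1, 2 or 3 or mutant 3 or 6, and Tagln without wildtype 1, 2 or 3 or mutant 3 or 5. Of 26 TGF-beta pathway components, 11 rose and 1 fell (camera adjusted p = 5.2e-05; adjusted p = 0.51 with an estimated correlation; 14 and 1 adjusted over the list alone). They included the fibrillin genes Fbn1, up 1.84-fold, and Fbn2, up 1.67-fold, and the co-receptor gene Tgfbr3, up 1.53-fold. The component that fell, the decorin gene Dcn, was 1.35-fold lower, is named after its value was seen, and lost its call without wildtype 1 or 2. The lists share 8 measured genes, Thbs1 among them, of which 4 were called higher, so their results are not independent. Without wildtype 1, 7 targets and 5 components were called higher and 0 lower, and without wildtype 3, 9 targets and 7 components were called higher and 1 of each lower. With exon length removed, 12 targets and 7 components were called higher, and 0 targets and 1 component lower (edgeR), so Id1, Acta2 and Tagln lost their calls.

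Of 21 macrophage and myeloid markers, 6 rose and 1 fell (camera adjusted p = 0.00017; adjusted p = 0.51 with an estimated correlation; 10 and 1 adjusted over the list alone). The lysozyme gene Lyz2 rose 4.59-fold from 30.9 ± 0.209 to 142 ± 23.9 CPM (adjusted p = 3.49e-08), and the lysosomal marker Cd68 2.50-fold from 9.64 ± 1.27 to 24.1 ± 2.54 CPM (adjusted p = 3.18e-05). Ctss, a cathepsin gene, rose 1.93-fold and the integrin gene Itgam 2.3-fold. The member that fell, Lyve1, a marker of some tissue macrophages and of lymphatic vessels, went from 13.6 to 6.96 CPM and is named after its value was seen. It lost its call without wildtype 1 or 2, and its log2 fold change ran from -1.19 to -0.43 over the libraries left out in turn. General macrophage markers chosen after their values were seen did not pass the test: Csf1r stood at 43.6 ± 6.28 CPM in wildtype and 48.2 ± 5.34 in mutant, C1qa at 52.3 ± 5.17 and 56.9 ± 10.8, and Aif1 at 2.61 ± 0.938 and 2.75 ± 0.726. Without wildtype 1, 6 macrophage members were called higher. With exon length removed, 12 macrophage members were called higher and 0 lower.

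Of 14 erythroid markers, 6 rose and 1 fell, with a median log2 fold change of 1.65 (camera adjusted p = 0.00017; adjusted p = 0.51 with an estimated correlation; 10 and 1 adjusted over the list alone). Slc4a1, the red cell anion exchanger, rose 2.95-fold from 1.73 ± 0.74 to 5.09 ± 1.19 CPM (adjusted p = 0.00295), and Slc25a37, a mitochondrial iron importer, rose 1.57-fold. Globin genes took between 0.0526% and 0.087% of all counts in wildtype libraries and between 0.178% and 0.842% in mutant libraries. Klf1, the transcription factor of red cell precursors, was the member that fell, from 1.92 ± 0.435 to 0.871 ± 0.181 CPM, is named after its value was seen, and lost its call without wildtype 1 or 2. Without wildtype 1, 2 erythroid members were called higher and 0 lower, and Slc25a37 lost its call.

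**Figure D2:**
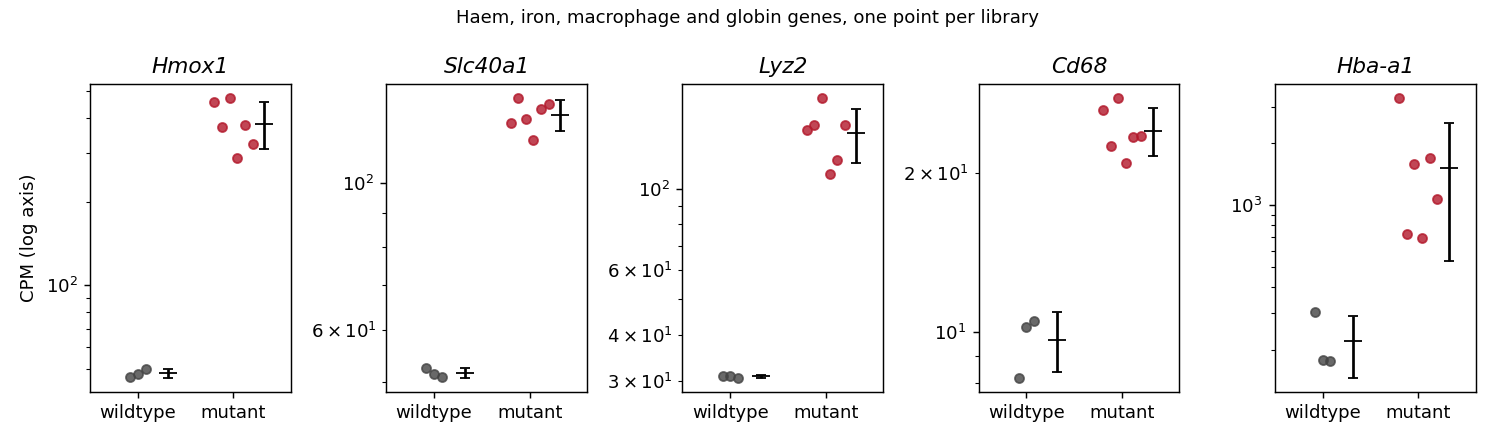
CPM on a log axis of Hmox1, the iron exporter gene Slc40a1, Lyz2, Cd68 and Hba-a1 in each of the 3 wildtype and 6 mutant libraries, with the group mean and SD as a bar beside the points. Mean Hmox1 was 48.2 CPM in wildtype and 382 CPM in mutant libraries, and the mutant libraries lie above the wildtype libraries in every panel.

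Vascular endothelial markers rose, with 11 of 20 higher and 1 lower (camera adjusted p = 0.00014; adjusted p = 0.51 with an estimated correlation; 14 and 1 adjusted over the list alone). Cdh5, the cadherin of endothelial junctions, rose 1.59-fold from 92.9 ± 12.8 to 148 ± 13.2 CPM (adjusted p = 0.000813), the VEGF receptor gene Kdr 1.5-fold and Robo4 1.53-fold, while the transcription factor gene Erg fell 1.43-fold. Without wildtype 1 the list held 1 gene called higher and 1 lower, and Kdr and Robo4 were no longer called, while without wildtype 3 it held 6 and 1. Pericyte and smooth muscle markers split, with 4 of 16 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.88). Abcc9, a potassium channel subunit of pericytes, rose 2.35-fold and Cspg4 1.95-fold. The smooth muscle contractile genes Actg2 and Cnn1 fell 1.85-fold and 1.66-fold. Without wildtype 1 this list held 3 genes called higher and 3 lower, and without wildtype 3, 4 and 2.

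Notch pathway genes rose, 7 of 17 higher and 0 lower (camera adjusted p = 0.0058; adjusted p = 0.51 with an estimated correlation; 8 and 0 adjusted over the list alone). The receptor genes Notch2 and Notch3 rose 1.53-fold and 1.32-fold and the ligand gene Jag1 1.39-fold. All 7 called members, these among them, lost their calls without wildtype 1. Without wildtype 3, 4 members were called higher, and Jag1 was not. Of 14 Hippo-YAP targets, 6 rose and 0 fell (camera adjusted p = 0.0081; adjusted p = 0.54 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone). Ccn2, a matricellular target shared with TGF-beta signalling, rose 1.71-fold from 74.4 ± 7.89 to 128 ± 26.9 CPM, Dlc1 1.51-fold and Tead1 1.45-fold. Without wildtype 1, 1 Hippo-YAP target was called higher, and Dlc1 and Tead1 lost their calls. Of 19 genes in the FGF and MAPK feedback list, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.51 with an estimated correlation). These were Spred2, up 1.44-fold, and Dusp6, up 1.26-fold, and Dusp6 was not called without wildtype 1 or wildtype 3.

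Cholesterol biosynthesis genes fell, 9 of 23 lower and 0 higher (camera adjusted p = 0.011; adjusted p = 0.51 with an estimated correlation; 10 and 0 adjusted over the list alone). Fdps, which makes farnesyl diphosphate, fell 1.41-fold from 73.9 ± 4.36 to 52.5 ± 3.29 CPM (adjusted p = 0.00188), and Tm7sf2 1.67-fold. Without wildtype 1, 1 gene of this list was called lower and Tm7sf2 lost its call, and without wildtype 3, 3 genes were called lower. Corneal stroma keratocyte markers fell, 7 of 17 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.54 with an estimated correlation). The keratan sulfate proteoglycan genes Kera and Lum fell 1.84-fold and 1.46-fold, and Tkt fell 1.33-fold from 1108 ± 73.3 to 834 ± 47.7 CPM (adjusted p = 0.00471). The keratocyte list lost its call with exon length removed (adjusted p = 0.064) and without wildtype 2 or mutant 1, 3, 4 or 5, with a range of 0.014 to 0.15 over the libraries left out in turn. Without wildtype 1, 2 of its genes were called lower, and Kera and Lum lost their calls. Kera also lost its call with exon length removed (edgeR adjusted p = 0.0516). The keratocyte gene that rose, the bicarbonate transporter gene Slc4a4, was 1.32-fold higher, is named after its value was seen, and was not called without wildtype 1 or wildtype 3. Of 36 anterior segment developmental regulators, 7 rose and 0 fell (camera adjusted p = 0.043; adjusted p = 0.54 with an estimated correlation; 8 and 0 adjusted over the list alone). Svep1 rose 2.08-fold and Cyp1b1 1.38-fold, but the list was not called with exon length removed (adjusted p = 0.14) or without wildtype 1 (adjusted p = 0.38) or mutant 2, with a range of 0.0091 to 0.38 over the libraries left out in turn. Cyp1b1 lost its call without wildtype 1, where 1 member was called, and 2 members were called without wildtype 3.

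**Figure D3:**
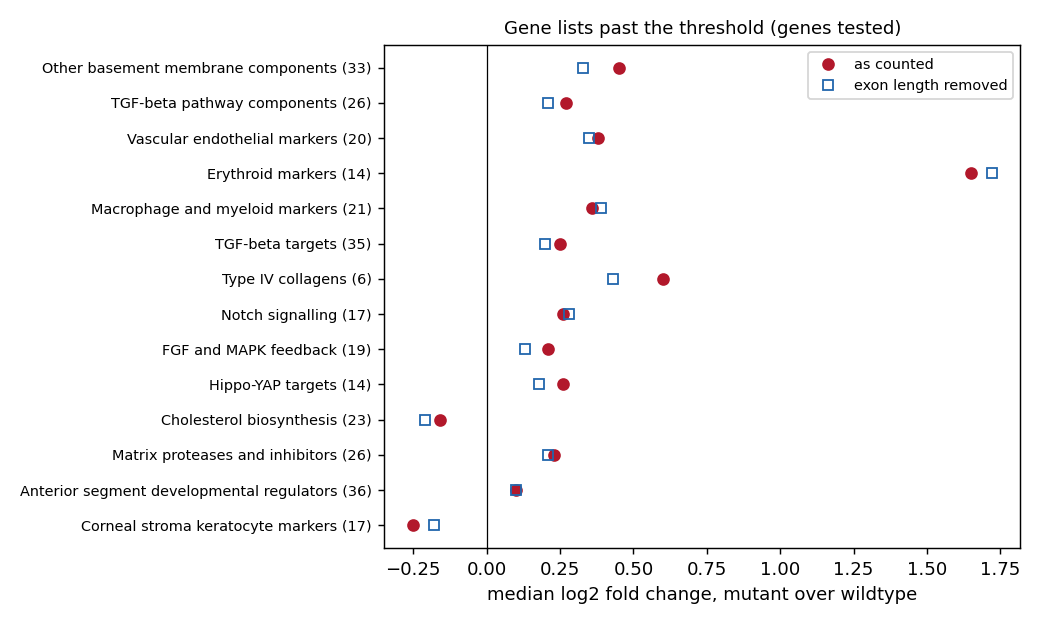
Median log2 fold change, mutant over wildtype, of the 14 called gene lists, with the number of genes tested in brackets, as counted (filled circles) and with exon length removed (open squares). Other basement membrane components moved from 0.45 to 0.33 and erythroid markers from 1.65 to 1.72.

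In all, 14 of 41 lists were called, 12 higher and 2 lower, and 27 were not. With exon length removed 18 were called (camera), 12 of them also called as counted, and 0 with an estimated correlation. Besides lists given below, those gained were mitochondrially encoded genes (adjusted p = 0.0014) and corneal endothelium and trabecular meshwork markers (adjusted p = 0.016). Immediate early genes (adjusted p = 0.022) and heat shock genes (adjusted p = 0.044) were gained as well. With an estimated correlation 0 of the 41 were called (camera, 2 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 13. Other splits of the 9 libraries into 3 and 6 also gave many list calls: 8 of the 84 splits, the real one included, called 14 or more. Those besides the real one held 2 or 0 wildtype libraries in the smaller group and so kept part of the genotype difference. Among the lists not called, 0 of 32 proliferation genes rose or fell (edgeR, also adjusted over the list alone; camera adjusted p = 0.99, with a test direction below 0 beside a median of 0.05). Of 30 genes of the unfolded protein response and endoplasmic reticulum stress, 6 rose and 1 fell (camera adjusted p = 0.35; 7 and 2 adjusted over the list alone). The member that fell was Xbp1, 1.23-fold lower, also named after its value was seen. Without wildtype 1, 1 gene of this list was called higher, without wildtype 3, 2 were, and Xbp1 was called in neither. With exon length removed the list was called higher (camera adjusted p = 0.048; adjusted p = 0.46 with an estimated correlation). Corneal epithelium markers had 6 of 29 higher and 1 lower (camera adjusted p = 0.38, and 0.0087 with exon length removed, or 0.46 with an estimated correlation as well; 7 and 1 adjusted over the list alone). Without wildtype 1, 1 of these was called higher, and without wildtype 3, 1 higher and 1 lower. Lens markers had 0 of 11 higher and 1 lower (camera adjusted p = 0.089; 0 and 1 adjusted over the list alone), a call lost without wildtype 1. Interferon-stimulated genes had 1 of 25 higher and 0 lower (camera adjusted p = 0.49; 0 and 0 adjusted over the list alone), a call lost without wildtype 1, 2 or 3 or mutant 4.

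Fold changes followed gene length. The labels do not decide whether this trend came from genotype, RNA quality or library preparation. Across genes, which are not independent replicates, the log2 fold change correlated with annotated exon length (Spearman 0.43). The median log2 fold change ran from -0.30 in the shortest of 8 bins of genes to 0.24 in the longest. In the shortest bin 37 genes were called higher and 400 lower, and in the longest 526 and 28. With the length trend removed from each library, a correction chosen after the data were seen, 2168 genes were called, of which 1741 had also been called in the same direction before, and 1293 of the earlier calls were lost. The counts then were 918 higher and 1250 lower. Of the 80 ribosomal protein genes, which are short and were picked as a group after the data were seen, 62 were lower and 0 higher (edgeR) with a median of -0.48. As a set they were called lower with the preset correlation (camera unadjusted p = 5e-23) and not with an estimated one, which was 0.67 (unadjusted p = 0.11; fry unadjusted p = 0.0048). Of these genes 46 were called lower with a median of -0.35 once exon length was removed, or 24 with a median of -0.22 once principal transcript length was removed. Without wildtype 1, 20 of them were called lower, with a median of -0.38. Their median stayed below 0 and 0 were called higher (edgeR) under TMM, DESeq2 size factor and upper quartile scaling, with medians of -0.48, -0.47 and -0.50.

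**Figure D4:**
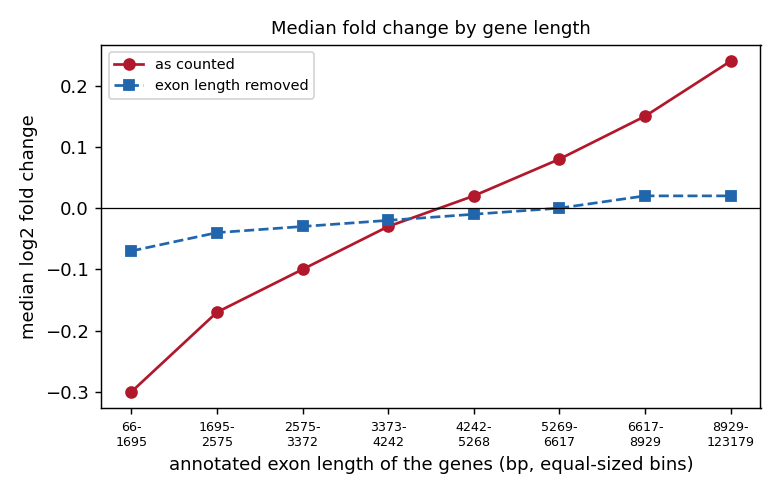
Median log2 fold change, mutant over wildtype, of genes in 8 equal-sized bins of annotated exon length in bp, as counted (circles) and with exon length removed (squares). The median ran from -0.30 in the shortest bin to 0.24 in the longest as counted, and from -0.07 to 0.02 after the correction.

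The libraries also split on Gm42418, a gene model that overlaps ribosomal RNA sequence. It took between 4.11% and 6.91% of counts in wildtype 1 and mutants 1, 3, 4, 5 and 6, and between 0.0663% and 0.0708% in wildtype 2, wildtype 3 and mutant 2. Mitochondrial genes took between 2.12% and 2.19% of counts in wildtype and between 2.37% and 3.4% in mutant libraries. With genotype in the same edgeR model, the split on Gm42418 called 2 genes, Lars2 and Gm42418. The mutant minus wildtype difference in Col4a1 was 0.91 on the log2 scale within the first set, with 1 wildtype and 5 mutant libraries, and 0.67 within the second, with 2 wildtype and 1 mutant. Basement membrane genes had medians of 0.65 and 0.33 in these sets, TGF-beta targets 0.35 and 0.23, macrophage markers 0.41 and 0.34, and erythroid markers 1.38 and 1.03. Wildtype 1, wildtype 2 and mutants 1 to 3 held Y-linked RNA, and the other libraries held Xist. Col4a1 differed by 0.71 within the Y-linked set, with 2 wildtype and 3 mutant libraries. Within the Xist set, with 1 wildtype and 3 mutant libraries, it differed by 0.76. With 1 wildtype library in the Xist set, whether the genotype effect differs between the sets cannot be decided.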

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

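The tests of gene length and of the ribosomal RNA split given here were chosen after the result was seen. Of 69 values tested over the 6 mutant libraries, 22 genes and 47 list scores, 4 had 1 library far from the others by Dixon's ratio of gap to range, and chance gives about 1 in 20. Treml4 stood at 2.19 log2 CPM in mutant 1 against 0.09 to 0.87 in the other mutant libraries (ratio 0.629). Ramp1 stood at -1.54 in mutant 1 against 0.80 to 1.73 (ratio 0.715). The mean score of the lens markers was 0.30 in mutant 1 against 0.92 to 1.26 (ratio 0.639). The score of the other basement membrane components was 7.56 in mutant 4 against 7.21 to 7.32 (ratio 0.684).

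The rise of the other basement membrane genes came with a trend of expression on gene length that was steepest in mutant 4 (Spearman 0.47 across genes, which are not independent replicates) and ran the other way in wildtype 1, 2 and 3 (-0.42, -0.19 and -0.39), while the other mutant libraries lay between 0.01 and 0.26. With gene length removed, the list's median log2 fold change was 0.29 under the length that left less of it, with a range of 0.21 to 0.38 over both lengths and each library left out. This argues against annotated length as the whole cause, while part of the rise went with it. The range is not a confidence interval. With exon length removed and an estimated correlation the list was not called (camera adjusted p = 0.46). With the ribosomal RNA split as a covariate the median was 0.53, with a range of 0.33 to 0.67, which argues against that split as the whole cause. Each end of that range rests on 1 library. Without wildtype 1 (0.33) the genotype effect compares mutant 2 alone with wildtype 2 and 3. Without mutant 2 (0.67) it compares the other mutants with wildtype 1 alone. The mutation, and a trend on a property of the RNA that annotated length does not capture, stay open as explanations and were not tested. Of the list's genes, 10 were called higher without wildtype 1 against 24 with all libraries.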

How the results depend on the processing

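The corrections for gene length and for the ribosomal RNA split were chosen after the data were seen. Against 3034 calls (1535 higher, 1499 lower), limma-voom with quality weights gave 4694 (2359 and 2335), a lens score covariate 1370 (772 and 598), a threshold of 0.01 1032 (520 and 512), and a test against a fold of 1.2 369 (214 and 155). Removing principal transcript length gave 1726 (741 and 985), the ribosomal RNA covariate 1877 (938 and 939), and exon length with that covariate 1509 (613 and 896). Exon length alone gave 918 higher, with GC content 957 higher, without mutant 1 979 higher, and without mutant 4 1965 calls, 829 higher. The share of calls that were higher was 43.7% with upper quartile factors, which is lower than the share by TMM, and 42.3% with exon length removed. Leaving out each library in turn gave 538 to 3265 calls, 303 to 1688 higher and 235 to 1577 lower, lowest without wildtype 1 and highest without mutant 1. Without wildtype 2, which leaves as many samples as without wildtype 1, there were 2913 calls, so sample number alone does not account for the loss. The cause of these changes was not tested. With an estimated correlation the TGF-beta target list had an adjusted p of 0.51 and 0 lists were called (camera, against 13 by fry and 2 at an unadjusted p under 0.05).

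The shared replicate numbers are not said to mark pairs, and they were not used as pairs in the main fit. With each group's mean subtracted from log2 CPM, same-numbered libraries correlated at 0.09, 0.03 and -0.10. Not every sample correlated best with its own number. So few pairs cannot show whether the numbers mark a batch or litter. A replicate block gave 1485 calls (814 higher, 671 lower), of which 1406 were shared with the fit without it. Mutants 4, 5 and 6 have no wildtype library of the same number, so in that fit they added nothing to the genotype effect. Its count therefore reflects fewer samples as well as the block. Col4a1 and Col4a2 stayed past the test in every leave-one-out fit, with log2 fold changes of 0.63 to 0.85 and 0.56 to 0.82. Among 5385 checks of 193 single genes, 4718 kept their direction and side of the threshold, 541 lost a call and 122 gained one. A further 4 changed direction with no call before or after, and 0 changed direction with a call. Among 1200 checks of 40 lists, 1062 kept theirs, 47 lost a call and 50 gained one. A further 41 changed direction with no call before or after, and 0 changed direction with a call. DESeq2 gave no adjusted p for 1228 genes.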

Other observations

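The tests of the added lists, of gene length, of blood, of the region near Col4a1, of targets outside the matrix lists, of the ribosomal protein genes and of Hmox1 were chosen after the result was seen. Adjusted p-values of the added lists were taken over 6 lists, against 41 for those fixed before, so they are not comparable. Unadjusted, camera p with an estimated correlation was 0.011 for complement and coagulation and 0.02 for phagocytosis and the lysosome. It was 0.031 for the Notch list and 0.043 for the vascular endothelial list, both fixed before. Genes of phagocytosis and the lysosome rose, 13 of 23 higher and 1 lower with a median log2 fold change of 0.73 (camera adjusted p = 1.3e-08; adjusted p = 0.059 with an estimated correlation), and 3 of its genes also stand in a list fixed before. The scavenger receptor gene Cd36 rose 5.98-fold from 5.73 ± 1.04 to 34.3 ± 2.17 CPM (SD, n = 3 and 6, edgeR adjusted p = 9.2e-09), Mpeg1 4.22-fold and the lectin receptor gene Clec4n 5.84-fold, while Ctsk was 1.28-fold lower, a call lost without wildtype 1 or wildtype 3. Of 18 genes for red cell clearance and iron recycling, 7 rose and 1 fell (camera adjusted p = 3.0e-04; adjusted p = 0.10 with an estimated correlation), and 4 of its genes also stand in a list fixed before. Vcam1 was the member that fell, 1.26-fold, a call lost without wildtype 1 or wildtype 2. Slc40a1, which exports iron from cells, rose 2.45-fold from 51.6 ± 0.824 to 126 ± 6.64 CPM (edgeR adjusted p = 3.49e-08). Spic, a transcription factor gene of iron-recycling macrophages, had 2 counts in wildtype and 212 in mutant libraries, a ratio of 46 with an exact 95% counting interval of 12.6 to 383 that covers counting error only, and both wildtype counts lay in wildtype 3.

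Complement and coagulation genes rose, 11 of 21 higher and 0 lower (edgeR; camera adjusted p = 2.3e-06; adjusted p = 0.059 with an estimated correlation), and 4 of its genes stand in a list fixed before. C3ar1 rose 2.79-fold, Vwf 2.56-fold and C4b 2.32-fold. Of 16 NRF2 targets, which answer oxidative stress, 7 rose and 2 fell (camera adjusted p = 0.017; adjusted p = 0.14 with an estimated correlation), with Srxn1 up 1.47-fold and Gstm1 up 1.57-fold. With exon length removed and an estimated correlation, camera adjusted p over the 6 added lists was 0.031 for phagocytosis and 0.031 for complement. It was 0.032 for NRF2 targets and 0.063 for red cell clearance. The sterol efflux genes Abcg1 and Abca1 rose 2.15-fold and 2.06-fold, while their list of 11 LXR targets was not called (camera adjusted p = 0.086) but was called higher with exon length removed (camera adjusted p = 0.01; adjusted p = 0.17 with an estimated correlation). Of 14 blood leukocyte markers 1 rose, Itgal, which lost its call when wildtype 1, 2 or 3 or mutant 3, 4 or 5 was left out, and when adjusted over the list alone. Their list was not called (camera adjusted p = 0.086, median 0.17) but was called higher with exon length removed (camera adjusted p = 0.005, median 0.37; adjusted p = 0.13 with an estimated correlation). The abundant neutrophil genes S100a8 and S100a9 stood at 4.23 ± 1.77 and 6.64 ± 2.97 CPM in wildtype and 4.00 ± 1.32 and 5.70 ± 1.93 CPM in mutant libraries (edgeR adjusted p = 0.883 and 0.642).

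For the number of genes called, 1 of the 84 splits of the 9 libraries into 3 and 6, the real one, gave as many. It had 3034 calls against at most 2 in any other split. The same held for genes called higher (1535 against at most 2, 1 split) and lower (1499 against at most 1, 1 split). A share of 1 in 84 is the smallest these splits can give, so chance was unlikely but not excluded for these counts. Every other split mixes the genotypes in its larger group, so a real difference widens the spread there and lowers its calls. For the list tests chance stays open. As many lists were called in 8 of the 84 splits, the real one included, 14 in the real one against 18 in the highest other. Those besides the real one held 2 or 0 wildtype libraries in the smaller group and so kept part of the genotype difference. They therefore do not show how often chance alone calls as many lists. The unadjusted camera p of the TGF-beta targets, 2.4e-05, was reached in 9 splits, the real one included, the smallest other being 1.8e-08. It was also reached with wildtype 1, mutant 3 and mutant 5 as the smaller group (1.1e-05), a split with the same share of wildtype libraries in both groups.

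The macrophage list and the erythroid list, which holds the haemoglobin genes, were each called higher under the preset correlation and not with an estimated one (adjusted p = 0.51 for each), and no test linked the pair. With gene length removed, the median of the macrophage markers was 0.39, with a range of 0.39 to 0.60 over both lengths and each library left out. These markers are short, with a median exon length of 1732 bp, and genes of 1695 to 2575 bp had a median log2 fold change of -0.17. The length trend thus ran against their rise, so removing it could hardly have taken the rise away and is no separate test. Blood left in the tissue cannot be told apart from a change in the tissue: the macrophage score rose by 0.45 log2 CPM (exact permutation p = 0.0119), 0.21 more than the blood leukocyte score (exact permutation p = 0.286). The leukocyte score itself differed by 0.24 (exact permutation p = 0.214). Its list was called with exon length removed (camera adjusted p = 0.005) and not as counted. The permutation test asked only whether the score differed, not whether it rose as far as the haemoglobin RNA. Hba-a1 and Hba-a2 rose by 2.79 and 2.71 log2. Had blood been the score's only source, blood that raised both in proportion would have moved the score about as far. The gap in size argues against blood as the whole source of the haemoglobin RNA in that case. Where other cells add to the score, blood as the source stays open. An effect of the mutation on the tissue stays open and was not tested.

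The 80 ribosomal protein genes had a median of -0.48 and 62 were called lower, or 20 without wildtype 1, but as a set they were called with the preset correlation (camera unadjusted p = 5e-23) and not with an estimated one (unadjusted p = 0.11). Part of the fall went with gene length. With principal transcript length removed the median was -0.22, with a range of -0.39 to -0.19 over both lengths and each library left out, which argues against annotated length as the whole cause. The mutation, and a trend on a property of the RNA that annotated length does not capture, stay open and were not tested.

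Within 20 Mb of Col4a1, 24 of 145 genes were called, 16.6% against 19.2% elsewhere (odds ratio 0.835, 95% interval 0.514 to 1.31, Fisher's exact two-sided p = 0.46), so an effect of DNA linked to the mutation was neither shown nor excluded. The hypothesis that TGF-beta targets rose apart from matrix genes was tested on the 26 targets in no matrix list. These still included the fibronectin gene Fn1, itself a matrix gene. Their median was 0.27, with 10 higher and 3 lower (camera p = 7e-05, and p = 0.075 with an estimated correlation). They thus passed the test under the preset correlation only, and gene length was not removed in it. A rise apart from matrix genes was therefore not shown. Over the 6 mutant libraries, the only relation tested, Hmox1 and haemoglobin RNA had a Pearson r of 0.61 (exact permutation p = 0.188) and a Spearman rho of 0.66 (exact permutation p = 0.175), and r was 0.62 without the 2 farthest libraries, so a relation was not shown.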
